A study of Rattus norvegicus with 8 samples.

How the data were processed

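RNA of N27 cells was measured on 8 single-colour arrays, 2 each for control, Mn, MPP+ and 3-NPA, per the labels. The labels state growth in RPMI medium, RNA isolation with RNeasy columns and DNase, and Cy3 labelling of 500 ng of RNA with the Quick-Amp kit. Mn was given at 150 µM and MPP+ at 250 µM, each for 48 h, while the labels give no dose, time or vehicle for 3-NPA. Spot intensities were extracted with Agilent Feature Extraction 11.5.1.1 under its 1-colour protocol, with probe positions on the rn4 (RGSC v3.4) assembly, per the file headers. The processed signal is an intensity from which background was subtracted and which was detrended within the array, with a surrogate value where a spot was not above background and no normalization between arrays, per the file headers. All 8 arrays lay on 1 slide and came from 1 scan, and the 3-NPA arrays were extracted in the later of 2 runs, per the file headers. The deposited value table holds log2 values in 8 columns, and the tool that made it is not stated. Its columns had medians of -3.99 and -4.11 (control), -4.30 and -4.31 (Mn), -4.34 and -4.38 (MPP+) and -4.08 and -4.16 (3-NPA), and their 75th percentiles ran from 0.0101 to 0.0237. Each column correlated with the log2 processed signal of its array at 0.9966 or more, and from 96.6% to 97.9% of values lay within 0.05 of that signal minus 1 constant per array. The scale of the table was therefore taken as log2 relative to about the 75th percentile of each array, and how its remaining values were changed stays unknown.

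Each array held 62976 spots, of which 58717 were not control spots, for 30367 probes. Spots marked as population or non-uniformity outliers were left out, as were 39 probes with every spot marked on an array, and 30328 probes were used. The mean over the remaining spots of a probe was taken on the log2 scale, and the 75th percentile of each array over its probes was set to 0. A spot counted as well above background by the mark in the deposited files, and a probe where more than 0.5 of its spots did. This share was changed from at least 0.5, the looser rule below, after duplicate spots on the control arrays were seen to differ. The 19460 probes well above background on both arrays of at least 1 group were kept, and the brightest probe of each gene stood for it, which gave 16921 genes, 12019 of them with a gene symbol. A gene had more than 1 kept probe in 2311 cases, and its probes were called in opposite directions for 1 gene with Mn, 3 with MPP+ and 23 with 3-NPA. Of the probes used, 18345 (60.5%) matched an accession of the RefSeq table, 21373 had a gene symbol and 29469 a position. Probes without a symbol were tested and are not named.

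All 8 arrays entered 1 limma fit of group means with moderated variances, with 4 residual and 2.06 prior degrees of freedom, and p-values were adjusted by the method of Benjamini and Hochberg in each of the 6 comparisons. The smallest exact 2-sided permutation p for 2 arrays against 2 is 0.333, so no permutation test was used for single genes. The 35 gene lists, with 852 genes, covered stress responses, metals and iron, energy metabolism and mitochondria, lipids, the cell cycle and cell death, inflammation, transcription factors of early response, dopaminergic and neural genes, and markers of other cell types. They were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. Medians with bounds, in which genes dim on both arrays of 1 group were taken at their bound, are given where they differ. The genes, lists, comparisons, tests and most alternatives were chosen before the data were examined. Named genes were the 10 with the largest rise and the 10 with the largest fall among called genes with a symbol and no overlap between arrays for each toxin, 5 per direction for pairs of toxins, up to 4 members per list by smallest p, 22 fixed genes, and for the overlap those with the largest smallest change. Of the genes so chosen, some are not reported here. Members of lists written after the values were seen, markers used in the check for RNA of other cell types, and the genes left out of those later lists are named in the closing section as chosen after their values were seen.

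The alternatives were normexp background correction of raw means and local background with an offset of 50, quantile normalization, the median of each array, the deposited value table, no filter on dim probes, a filter on all 8 arrays, the mean over probes, every probe on its own, trend and robust variances, array weights, only the 4 arrays of a pair, a block of the replicate number, a change of at least 2-fold, and leaving out each array. Leaving out saturated probes was not run, since 0 spots were saturated. Added after seeing the data were the looser rule on background, leaving out probes whose spots differed by more than 1 on the log2 scale, the 6 arrays of the first extraction run alone, and the test of each list under every setting. The steps were tested on simulated data with 16921 genes. Changed genes were recovered at folds of 1.5, 2 and 4 in 11.9%, 59.7% and 90.9% of cases for Mn with 11 false calls, in 14.9%, 52.2% and 89.4% for MPP+ with 5 false calls, and in 1.49%, 61.2% and 90.9% for 3-NPA with 3 false calls. For 3-NPA the 1 shifted list was called and 0 of the others were by camera. R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, were used.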

Results

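The series measured gene expression in N27 cells, a line of immortalised rat mesencephalic cells described in the labels as dopamine producing, after exposure to a neurotoxin. Cells served as control, were given manganese (Mn, 150 µM for 48 h), or were given MPP+ (250 µM for 48 h), a compound known to inhibit respiratory complex I. A further group is labelled 3-NPA, taken here to mean 3-nitropropionic acid, a known inhibitor of succinate dehydrogenase, and its dose and time are not in the labels. Each of the 4 groups was measured on 2 single-colour arrays, all on 1 slide. The spots well above background numbered 34060 and 32711 on the control arrays, 37964 and 38033 on the Mn arrays, 41013 and 39832 on the MPP+ arrays, and 40345 and 41354 on the 3-NPA arrays. The 75th percentile of processed signal was 1157 and 1024 (control), 1124 and 1132 (Mn), 1279 and 1186 (MPP+), and 1075 and 1160 (3-NPA) intensity units, and 0 spots were saturated on each array. The number of arrays limits the precision of every value below.

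3-NPA was followed by the most called genes, then MPP+, then Mn. Of 16921 tested genes, 1294 passed for Mn against control (761 higher and 533 lower), 2362 for MPP+ (1265 higher and 1097 lower) and 6477 for 3-NPA (3769 higher and 2708 lower), at a limma adjusted p below 0.05 with n = 2 arrays per group. The difference was at least 2-fold for 466, 640 and 2039 of those genes. The higher share of the calls depended on the scaling. It was 58.8% for Mn as reported, 73.1% after quantile normalization and 70.1% with the median of each array in place of its 75th percentile. For MPP+ it was 53.6% as reported, 64.5% after quantile normalization, 71.4% with the median and 39.7% with the normexp background correction. For 3-NPA it was 58.2% as reported and 42.6% with the median. The median log2 fold change of all genes was -0.02 for Mn, 0.02 for MPP+ and 0.05 for 3-NPA as reported, and 0.06, 0.13 and -0.09 with scaling by the median, so small shifts of a gene group are relative to the scaling. Replicate arrays correlated across genes at 0.99 (control), 0.991 (Mn), 0.997 (MPP+) and 0.994 (3-NPA), against 0.973 to 0.989 between groups, and genes are not independent replicates. The first principal component held 43.8% of the variance and set the 3-NPA arrays (63.6 each) apart from the other arrays (-31.6 to -11.4). The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these arrays. The treated and control arrays did not overlap for 50.5% of genes in Mn, 63.5% in MPP+ and 71.9% in 3-NPA, where chance gives 33.3%. Below, "at least" marks a fold for a gene that was dim on both arrays of the lower group, which was then taken at each array's lowest signal well above background. Such a fold holds for the processed signal, and values with normexp are given where they were over 1.5 times closer to 0. Values after ± are standard errors from limma.

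**Figure D1:**
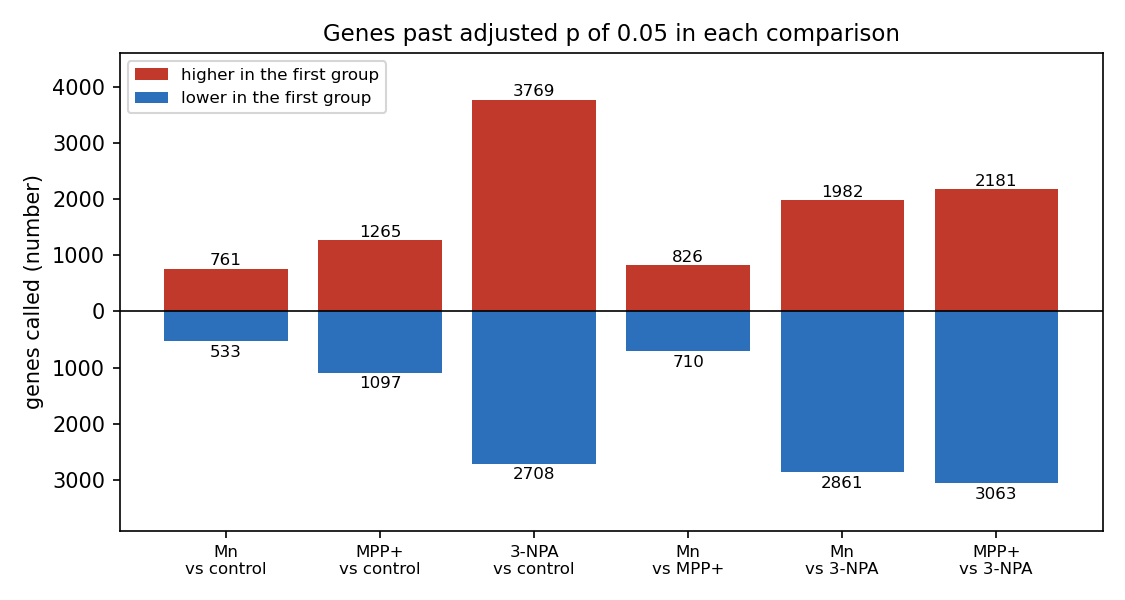
Number of genes called by limma in each of the 6 comparisons (horizontal axis, comparison, and vertical axis, number of genes), with genes higher in the first group above 0 and genes lower in it below 0. Among the comparisons with control, 3-NPA had 3769 higher and 2708 lower genes, MPP+ had 1265 and 1097, and Mn had 761 and 533.

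The comparison of Mn with control asks which transcripts change in these cells after exposure to manganese, a metal toxic to the basal ganglia. Nos2, the inducible nitric oxide synthase (chromosome 10, 65072394 to 65072453), was at least 4.40-fold higher (adjusted p = 0.0014), and Csf2, the cytokine GM-CSF, at least 2.74-fold. Mgp, an extracellular inhibitor of calcification (chromosome 4, 173910827 to 173910886), was 13.3-fold higher (log2 fold change 3.73 ± 0.13, adjusted p = 0.000579). Slc7a11, the cystine and glutamate exchanger (chromosome 2, 139241468 to 139241527), was 10.8-fold higher (log2 fold change 3.43 ± 0.10), and Srpx2, a secreted protein, at least 10.7-fold. Aldh1a1, a retinaldehyde dehydrogenase found in a subset of dopaminergic neurons (chromosome 1, 223773152 to 223773211), was at least 4.67-fold lower (adjusted p = 0.00296). Shc3, a neuronal signalling adaptor, had a log2 fold change of -2.19 ± 0.11. With normexp the log2 fold changes were 1.70 (Nos2), 1.5 (Csf2), 2.42 (Srpx2) and -1.09 (Aldh1a1).

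Of the 35 gene lists, 13 passed for Mn, 7 toward higher and 6 toward lower values, and 2 of them held with an estimated correlation. In the list of the ATF4 and amino acid response, which raises amino acid uptake and synthesis under stress, 18 of 37 tested members rose and the other 19 did not pass, and adjusted over the list alone 27 rose. The ATF4 list had a median log2 change of 0.54 (0.50 with bounds), camera adjusted p = 4.83e-14 (0.0442 with an estimated correlation). Its members included the pseudokinase gene Trib3 (1.87 ± 0.13), asparagine synthetase Asns (1.09 ± 0.09) and the cationic amino acid transporter Slc7a1 (0.94 ± 0.09), whose dimmer probe did not pass (0.76 ± 0.20). In the list of NF-kB and inflammatory genes, 10 of 21 tested members rose and the other 11 did not pass, and adjusted over the list alone 15 rose, with the chemokines Cx3cl1 (1.59 ± 0.11), Cxcl2 (1.80 ± 0.13) and Cxcl1 (1.15 ± 0.09). The NF-kB list had a median log2 change of 0.61, camera adjusted p = 9.86e-10 (0.0442 with an estimated correlation). In cholesterol synthesis, 15 of 25 tested members fell and the other 10 did not pass, and adjusted over the list alone 20 fell, with Insig1, a retainer of sterol regulators in the endoplasmic reticulum (-1.72 ± 0.10), farnesyl diphosphate synthase Fdps (-1.37 ± 0.13) and Acat2 (-0.84 ± 0.09). Cholesterol synthesis had a median log2 change of -0.56, camera adjusted p = 1.1e-13 (0.085 with an estimated correlation). Among p53 targets, 8 of 21 tested members rose, 1 fell and the other 12 did not pass, and adjusted over the list alone 10 rose and 1 fell. The p53 list had a median log2 change of 0.45, camera adjusted p = 0.000588 (0.119 with an estimated correlation). The nuclease gene Aen (1.59 ± 0.15), the Akt inhibitor Phlda3 (1.07 ± 0.13) and the p53 ligase Mdm2 (1.22 ± 0.16) rose, as did the brightest probe of the cell cycle inhibitor Cdkn1a (2.01 ± 0.13), whose other probe did not pass (0.14 ± 0.12). Among immediate early genes, 7 of 24 tested members rose and the other 17 did not pass, and adjusted over the list alone 14 rose and 3 fell, with the ERK phosphatase Dusp6 (2.11 ± 0.13), the AP-1 gene Fosl1 (1.97 ± 0.18) and Dusp5 (1.30 ± 0.17). The immediate early list had a median log2 change of 0.38, camera adjusted p = 1.66e-05 (0.188 with an estimated correlation). Among interferon-responsive genes, 7 of 23 tested members rose and the other 16 did not pass, and adjusted over the list alone 9 rose and 2 fell, with Rsad2 (2.26 ± 0.18), Usp18 (1.26 ± 0.14) and Irf7 (0.59 ± 0.08). The interferon list had a median log2 change of 0.19, camera adjusted p = 0.00197 (0.188 with an estimated correlation). In fatty acid synthesis and oxidation, 4 of 28 tested members fell and the other 24 did not pass, and adjusted over the list alone 1 rose and 10 fell, and the members that fell included the synthesis genes Elovl6 (-1.22 ± 0.11), Fasn (-0.89 ± 0.08) and Scd2 (-0.86 ± 0.10). The fatty acid list had a median log2 change of -0.13 (-0.06 scaled by the median), camera adjusted p = 0.00213 (0.188 with an estimated correlation). Among the markers of astrocytes, 4 of 8 tested members fell and the other 4 did not pass, and adjusted over the list alone 5 fell, with Ndrg2 (-1.0 ± 0.09) and the connexin gene Gja1 (-1.0 ± 0.10). The astrocyte list had a median log2 change of -0.48, camera adjusted p = 0.00353 (0.188 with an estimated correlation). The tricarboxylic acid cycle list shifted slightly down, although 2 of 23 tested members fell and the other 21 did not pass, and adjusted over the list alone 2 fell. Its median log2 change was -0.18 (-0.11 scaled by the median), camera adjusted p = 0.000588 (0.172 with an estimated correlation). In the proteasome, which also shifted down as a list, none of 31 tested members passed by limma, even adjusted over the list alone (at an unadjusted p under 0.05, 10 were lower). Its median log2 change was -0.15 (-0.08 scaled by the median and -0.04 with quantile normalization), camera adjusted p = 0.00306 (0.172 with an estimated correlation). The remaining lists that passed, mitosis, microglia markers and pan-neuronal genes, moved by medians of -0.12 (-0.05 with scaling by the median and -0.07 with quantile normalization), 0.45 (0.38 with bounds and 0.03 with normexp) and 0.33 (0.15 with normexp), with adjusted p = 0.188, 0.188 and 0.203 with an estimated correlation. These 3 were lost with the normexp background correction (adjusted p = 0.0656, 0.112 and 0.062), mitosis also without control replicate 2 (0.256). Microglia markers were lost without control replicate 2 (0.149) or Mn replicate 2 (0.0913), and pan-neuronal genes without control replicate 1 (0.0972). With no filter on dim probes those 3 lists did not pass, and neither did the tricarboxylic acid cycle, fatty acid, proteasome and astrocyte lists, and the pan-neuronal median turned to -0.92.

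Neither respiratory complex I nor the dopaminergic genes passed camera as lists in Mn. In complex I, none of 36 tested members passed by limma, even adjusted over the list alone (at an unadjusted p under 0.05, 1 was higher and 3 lower). Complex I had a median log2 change of -0.05, camera adjusted p = 0.265 (0.683 with an estimated correlation). The median was 0.02 scaled by the median, 0.0196 with quantile normalization and -0.03 with normexp. Among dopaminergic genes, 2 of 15 tested members fell and the other 13 did not pass, and adjusted over the list alone 1 rose and 2 fell. The dopaminergic list had a median log2 change of 0.06, camera adjusted p = 0.862 (0.885 with an estimated correlation). The mean was -0.21. The median was 0.13 scaled by the median, 0.17 with quantile normalization, -0.04 with normexp and 0.15 in the deposited value table. This list passed fry toward lower values (adjusted p = 0.0353), and complex I did not (0.217). Th, tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis (chromosome 1, 203164254 to 203164313), had a log2 fold change of -0.06 ± 0.10 (adjusted p = 0.73). The dopaminergic factor Nr4a2 (0.14 ± 0.12) and the succinate dehydrogenase genes Sdha (-0.13 ± 0.10) and Sdhb (-0.15 ± 0.09) did not pass. Neither did Ndufs1 of complex I (0.01 ± 0.11), haem oxygenase Hmox1 (0.05 ± 0.22), the endoplasmic reticulum chaperone Hspa5 (-0.07 ± 0.11), lactate dehydrogenase Ldha (0.02 ± 0.17) or the glucose transporter Slc2a1 (0.27 ± 0.09). Of the metal-handling genes fixed in advance, metallothionein Mt1 rose (0.48 ± 0.08), while Mt2A (0.33 ± 0.10), the zinc exporter Slc30a1 (-0.34 ± 0.08) and the brightest probe of the transferrin receptor Tfrc (0.48 ± 0.12) did not pass. The dimmer probe of Tfrc rose (1.02 ± 0.13, adjusted p over probes = 0.0125). The stress genes Ddit3 (0.55 ± 0.11) and Atf3 (0.45 ± 0.09) rose, as did the quinone reductase Nqo1 (1.17 ± 0.14, and 0.65 with normexp). Slc6a3, the dopamine transporter, was on the array and not well above background in any group. The count of 1294 fell to 569 without Mn replicate 1, 825 without Mn replicate 2, 675 without either MPP+ array and 653 without either 3-NPA array. It was 439 with array weights and 6 with only the 4 arrays of Mn and control. In that last fit Mgp, Slc7a11, Srpx2 and Csf2 passed and the other genes named for Mn did not. The calls of Mt1, Ddit3 and Atf3 were also lost without either control array, Mn replicate 1, either MPP+ array or either 3-NPA array. Those of Mt1 and Atf3 were also lost without Mn replicate 2. Array weights ended all 3 (adjusted p = 0.0861, 0.1 and 0.103). The Mn arrays lay in other slide columns than control, so Mn and column cannot be told apart.

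**Figure D2:**
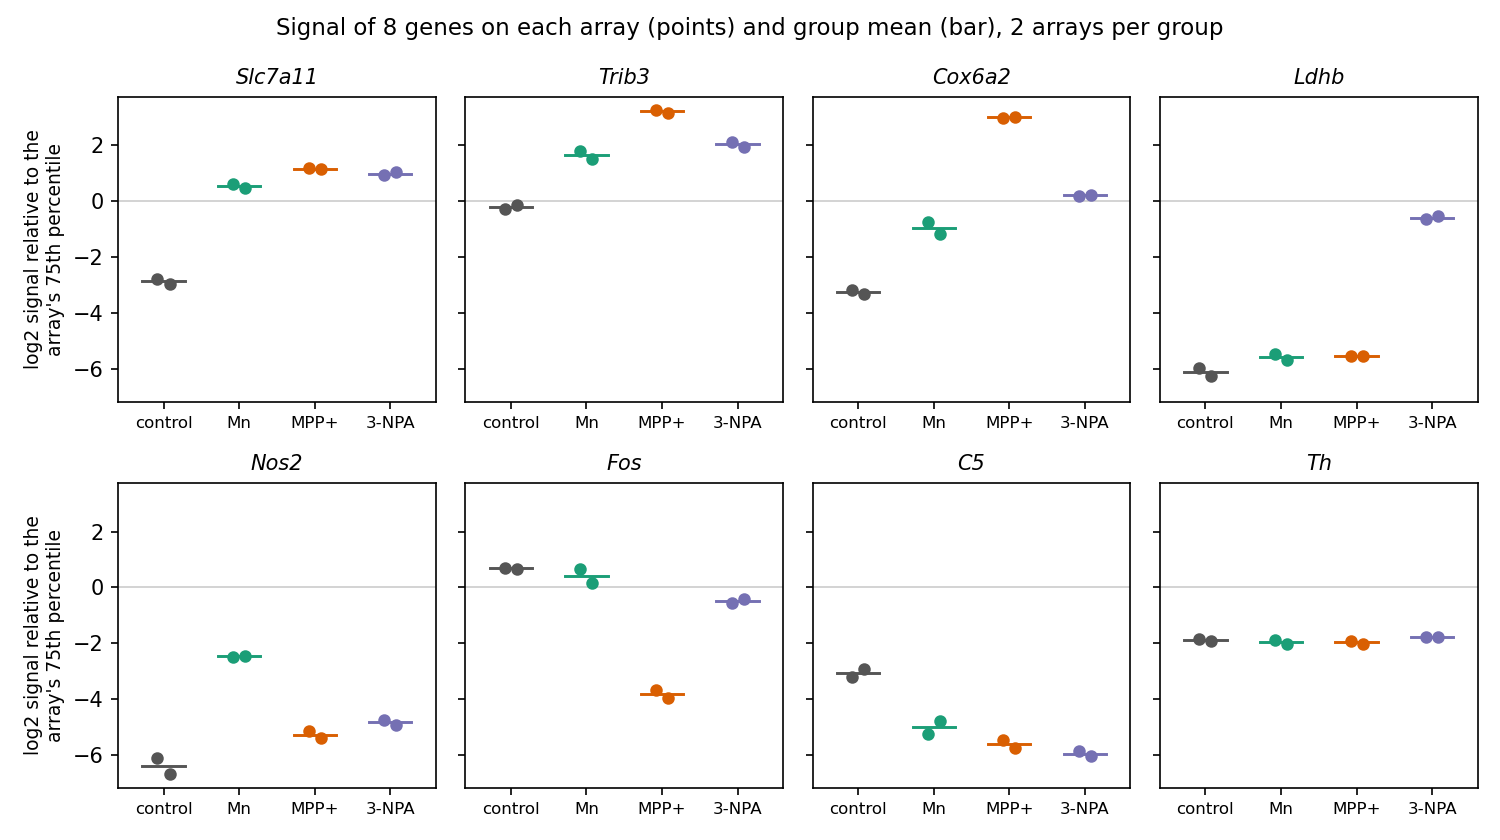
Signal of 8 genes on each of the 8 arrays (vertical axes, log2 signal relative to the array's 75th percentile), with 1 panel per gene, points for the arrays of control, Mn, MPP+ and 3-NPA and bars for the group means. Cox6a2 averaged 3.00 with MPP+ against -3.26 in control, Fos averaged -3.81 against 0.68, and Th lay at -1.94 with Mn against -1.89 in control.

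The comparison of MPP+ with control asks which transcripts follow exposure to a compound that inhibits complex I. Cox6a2, a subunit of cytochrome c oxidase best known from heart and skeletal muscle (chromosome 1, 187464580 to 187464639), was 77.1-fold higher (log2 fold change 6.27 ± 0.16, adjusted p = 0.000147), the most of the genes named for MPP+. The transporter gene Slc7a11 rose 16.5-fold (4.04 ± 0.10) and Slc7a3 10.5-fold (3.39 ± 0.14), as did the DNA repair gene Mgmt, 9.24-fold (3.21 ± 0.29), and Fut1, a fucosyltransferase gene, at least 11.2-fold. Trib3 (chromosome 3, 142664936 to 142664995) was 10.8-fold higher (3.43 ± 0.13) and the secreted stanniocalcin Stc2 at least 5.41-fold. Fos, an AP-1 transcription factor and immediate early gene (chromosome 6, 109561941 to 109562000), was 22.5-fold lower (-4.49 ± 0.19, adjusted p = 0.000517), and Egr2, another immediate early gene, 6.87-fold (-2.78 ± 0.19). Complement C5 was 5.83-fold lower (-2.54 ± 0.19). With normexp the log2 fold changes were 2.01 (Mgmt), 2.59 (Fut1), 1.58 (Stc2) and -1.35 (C5).

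Of the 35 lists, 13 passed for MPP+, 4 toward higher and 9 toward lower values, and 1 held with an estimated correlation. That list was the ATF4 and amino acid response, in which 35 of 37 tested members rose and the other 2 did not pass, and adjusted over the list alone 35 rose, with the stress transcription factor Ddit3 (2.47 ± 0.11) and Asns (1.96 ± 0.09). The ATF4 list had a median log2 change of 1.24 (1.21 with bounds), camera adjusted p = 2.62e-25 (0.0288 with an estimated correlation). In cholesterol synthesis, 20 of 25 tested members fell and the other 5 did not pass, and adjusted over the list alone 22 fell, with Insig1 (-1.78 ± 0.10), Fdps (-1.48 ± 0.13) and Hmgcs1 (-0.93 ± 0.09). Cholesterol synthesis had a median log2 change of -0.76, camera adjusted p = 1.76e-14 (0.115 with an estimated correlation). In fatty acid synthesis and oxidation, 1 of 28 tested members rose, 12 fell and the other 15 did not pass, and adjusted over the list alone 1 rose and 16 fell, with Scd2 (-1.25 ± 0.10), Elovl6 (-1.21 ± 0.11) and Fasn (-1.06 ± 0.08). The fatty acid list had a median log2 change of -0.40, camera adjusted p = 3.11e-06 (0.154 with an estimated correlation). Among immediate early genes, 3 of 24 tested members rose, 10 fell and the other 11 did not pass, and adjusted over the list alone 5 rose and 11 fell, with the MAP kinase phosphatase Dusp1 (-2.23 ± 0.12) and Ier2 (-2.0 ± 0.14). The immediate early list had a median log2 change of -0.26, camera adjusted p = 0.0246 (0.39 with an estimated correlation). The median was -0.15 scaled by the median. Among mitochondrial chaperones and proteases, 2 of 17 tested members rose and the other 15 did not pass, and adjusted over the list alone 3 rose, with the chaperone Hspa9 (1.21 ± 0.11). The mitochondrial chaperone list had a median log2 change of 0.24, camera adjusted p = 0.0183 (0.184 with an estimated correlation). In mitosis, 8 of 30 tested members fell and the other 22 did not pass, and adjusted over the list alone 10 fell, with the kinase gene Plk1 (-0.58 ± 0.09). Mitosis had a median log2 change of -0.24, camera adjusted p = 4.53e-05 (0.154 with an estimated correlation). The median was -0.13 scaled by the median. Among p53 targets, 7 of 21 tested members rose, 1 fell and the other 13 did not pass, and adjusted over the list alone 9 rose and 1 fell, with Aen (1.74 ± 0.15), Ccng1 (1.36 ± 0.13), Phlda3 (1.16 ± 0.13) and the brightest probe of Cdkn1a (1.39 ± 0.13), whose other probe did not pass (-0.11 ± 0.12). The p53 list had a median log2 change of 0.43 (0.36 with bounds), camera adjusted p = 0.00684 (0.155 with an estimated correlation). The median was 0.24 with normexp. Among hypoxia-responsive genes, 2 of 23 tested members rose, 6 fell and the other 15 did not pass, and adjusted over the list alone 2 rose and 8 fell. The hypoxia list had a median log2 change of -0.24, camera adjusted p = 0.00684 (0.155 with an estimated correlation). The median was -0.12 scaled by the median. The vasodilator gene Adm (-1.31 ± 0.08), the lipoprotein lipase inhibitor Angptl4 (-1.04 ± 0.08) and Ankrd37 (-1.01 ± 0.09) fell, while Vegfa, the vascular growth factor, rose (1.11 ± 0.11). Among NRF2 antioxidant targets, 6 of 26 tested members rose, 1 fell and the other 19 did not pass, and adjusted over the list alone 8 rose and 1 fell, led by Nqo1 (1.5 ± 0.14, and 0.86 with normexp). The NRF2 list had a median log2 change of 0.33 (0.30 with bounds), camera adjusted p = 0.0246 (0.197 with an estimated correlation). The median was 0.19 with normexp. Among astrocyte markers, 1 of 8 tested members rose, 4 fell and the other 3 did not pass, and adjusted over the list alone 1 rose and 4 fell, with the aldolase gene Aldoc (-1.92 ± 0.13), Ndrg2 (-1.10 ± 0.09) and Gja1 (-1.03 ± 0.10). The astrocyte list had a median log2 change of -0.50, camera adjusted p = 0.017 (0.218 with an estimated correlation). The proteasome, DNA replication and glycolysis lists passed at medians of -0.10, -0.16 and -0.14, with adjusted p = 0.197 each with an estimated correlation, and scaling by the median gave 0.01, -0.05 and -0.03. Glycolysis held 1 gene that rose and 4 that fell, DNA replication 1 and 2, and the proteasome 1 that fell.

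Neither list of respiratory chain subunits passed after MPP+. In complex I, none of 36 tested members passed by limma, even adjusted over the list alone (at an unadjusted p under 0.05, 2 were higher and 5 lower). Complex I had a median log2 change of -0.03 (0.08 scaled by the median and 0.0181 with normexp), camera adjusted p = 0.592 (0.816 with an estimated correlation). In complexes II to V and the tricarboxylic acid cycle, none of 36 and 23 tested members passed by limma, even adjusted over the list alone. At an unadjusted p under 0.05, 2 and 5 were higher and 4 and 2 lower. The fry test, run in place of camera, also left these 3 lists above the threshold (adjusted p = 0.536, 0.911 and 0.0564). Th had a log2 fold change of -0.09 ± 0.10 (adjusted p = 0.578). Nr4a2 (0.05 ± 0.12), Sdha (0.15 ± 0.10), Sdhb (0.10 ± 0.09), Ndufs1 (0.22 ± 0.11), Hmox1 (-0.39 ± 0.22), Hspa5 (-0.11 ± 0.11), Ldha (-0.61 ± 0.17), Slc2a1 (-0.30 ± 0.09), Tfrc (-0.38 ± 0.12) and Mt2A (0.28 ± 0.10) did not pass. Mt1 (0.82 ± 0.08) and Atf3 (0.50 ± 0.09) rose and Slc30a1 fell (-0.40 ± 0.08). The MPP+ arrays lay in another slide row than control. The 7 spike-in probes had an SD of log2 changes of 0.0511, against 0.518 over genes. Their mean of -0.29 leaves a difference in scaling open. The SD argues against slide row as the cause, except on areas, dim signals or single probes. The count of 2362 fell to 615 without MPP+ replicate 1, 477 without MPP+ replicate 2, 1288 without either 3-NPA array and 987 with only the 4 arrays of MPP+ and control. Of the lists, 8 passed without control replicate 1. Glycolysis, DNA replication and the proteasome did not pass without control replicate 1 (adjusted p = 0.071, 0.0731 and 0.071), control replicate 2 (0.0756 each) or MPP+ replicate 1 (0.0617, 0.123 and 0.0551), and glycolysis neither without either Mn (0.0501) or 3-NPA array (0.052). The NRF2 (0.0586) and astrocyte lists (0.071) were lost without control replicate 1 and the immediate early list without control replicate 2 (0.0515). With no filter on dim probes the lists of mitosis (0.4), fatty acids (0.187), hypoxia (0.674), immediate early genes (0.97), astrocyte markers (0.241), glycolysis (0.98), DNA replication (0.758) and the proteasome (0.885) did not pass. Normexp ended the calls of hypoxia (0.0541), glycolysis (0.0551), DNA replication (0.147) and the proteasome (0.33). Scaling by the median ended those of glycolysis (0.0519), DNA replication (0.101), the proteasome (0.17) and Slc30a1 (0.115), and the mean over probes those of glycolysis and DNA replication (0.0545 each). The hypoxia list was also lost with every probe on its own (0.151), and the NRF2 list with quantile normalization (0.0822) and with probes well above background on all 8 arrays (0.0981). With only the 4 arrays of MPP+ and control, glycolysis (0.0596), Atf3 (0.0635), Slc30a1 (0.0789) and Plk1 (0.0508) did not pass. The call of Atf3 was lost without control replicate 2 (0.054), MPP+ replicate 1 (0.118), MPP+ replicate 2 (0.132) or either 3-NPA array (0.0554). That of Slc30a1 was lost without control replicate 1 (0.0645), control replicate 2 (0.0613), MPP+ replicate 1 (0.146), MPP+ replicate 2 (0.17) or either 3-NPA array (0.0713), and that of Plk1 without MPP+ replicate 1 (0.0945) or MPP+ replicate 2 (0.0989).

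The comparison of 3-NPA with control asks which transcripts follow exposure to a compound that blocks the respiratory chain at succinate dehydrogenase. Ldhb, the lactate dehydrogenase subunit that favours conversion of lactate to pyruvate (chromosome 4, 180061921 to 180063949), was at least 16.2-fold higher (adjusted p = 6.37e-05), and Ldha, the other main subunit, had a log2 fold change of -0.89 ± 0.17. Metallothionein Mt3 (chromosome 19, 11284627 to 11284686) was at least 12.7-fold higher, the glutathione transferase Gsta1 at least 3.96-fold and the integrin Itga8 at least 4.99-fold. Rsad2, an antiviral interferon-responsive gene, was 14.7-fold higher (3.88 ± 0.18) and Slc7a11 14.6-fold (3.87 ± 0.10). Genes best known from the testis, Mro and Taf7l, were at least 7.15-fold and 5.68-fold higher. The chemokine Ccl20 (chromosome 9, 82443354 to 82443413) was 10.6-fold lower (-3.40 ± 0.16, adjusted p = 0.000122), the matrix protease Adamts1 8.25-fold (-3.04 ± 0.10), and Id2, an inhibitor of basic helix-loop-helix factors, 5.63-fold (-2.49 ± 0.16). The core histone genes Hist1h2bq (-2.98 ± 0.16) and Hist1h2bf (-2.94 ± 0.09) and the kininogen genes Kng1 (-2.55 ± 0.19) and Kng2 (-2.59 ± 0.22) fell, and each pair has close copies in the genome that a probe may not tell apart. With normexp the log2 fold changes were 3.15 (Ldhb), 1.82 (Gsta1), 1.82 (Itga8), 2.47 (Mro), 2.01 (Taf7l) and -1.62 (Kng1).

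Of the 35 lists, 16 passed for 3-NPA, 7 toward higher and 9 toward lower values. With an estimated correlation 0 passed camera, against 9 at an unadjusted p under 0.05, and 31 passed fry. In the ATF4 and amino acid response, 28 of 37 tested members rose and the other 9 did not pass, and adjusted over the list alone 29 rose, with Trib3 (2.26 ± 0.13), Ddit3 (1.74 ± 0.11) and Asns (1.23 ± 0.09). The ATF4 list had a median log2 change of 0.74, camera adjusted p = 8.33e-09 (0.114 with an estimated correlation). In cholesterol synthesis, 20 of 25 tested members fell and the other 5 did not pass, and adjusted over the list alone 1 rose and 21 fell, with Insig1 (-2.32 ± 0.10), Fdps (-2.27 ± 0.13) and Hmgcs1 (-1.18 ± 0.09). Cholesterol synthesis had a median log2 change of -0.94, camera adjusted p = 3.37e-10 (0.136 with an estimated correlation). In the proteasome, the complex that degrades tagged proteins, 21 of 31 tested members fell and the other 10 did not pass, and adjusted over the list alone 21 fell, with Psmd14 (-1.32 ± 0.09), Psmb1 (-1.02 ± 0.11) and Psmd13 (-0.86 ± 0.09). The proteasome had a median log2 change of -0.48, camera adjusted p = 3.14e-09 (0.103 with an estimated correlation). In complex I, 13 of 36 tested members fell and the other 23 did not pass, and adjusted over the list alone 13 fell, with Ndufs8 (-0.77 ± 0.13). Complex I had a median log2 change of -0.27 (-0.41 scaled by the median and -0.11 with quantile normalization), camera adjusted p = 3.84e-05 (0.184 with an estimated correlation). In complexes II to V, 1 of 36 tested members rose, 10 fell and the other 25 did not pass, and adjusted over the list alone 1 rose and 10 fell, with Atp5pf (-0.71 ± 0.10). Complexes II to V had a median log2 change of -0.18 (-0.33 scaled by the median and -0.0143 with quantile normalization), camera adjusted p = 0.00261 (0.43 with an estimated correlation). In the tricarboxylic acid cycle, 8 of 23 tested members fell and the other 15 did not pass, and adjusted over the list alone 8 fell, with Sucla2 (-1.13 ± 0.09), Pdhb (-1.10 ± 0.11) and Mdh1 (-0.90 ± 0.14). The list had a median log2 change of -0.24 (-0.38 scaled by the median and -0.10 with quantile normalization), camera adjusted p = 0.00223 (0.167 with an estimated correlation). Sdhb of succinate dehydrogenase fell (-0.41 ± 0.09, and -0.26 with quantile normalization) and Sdha did not pass (0.13 ± 0.10). Among NRF2 antioxidant targets, 15 of 26 tested members rose, 1 fell and the other 10 did not pass, and adjusted over the list alone 17 rose and 1 fell, with Nqo1 (2.63 ± 0.14), Gsta4 (1.71 ± 0.11) and Srxn1 (1.64 ± 0.11). The NRF2 list had a median log2 change of 0.55 (0.49 with bounds), camera adjusted p = 0.00223 (0.167 with an estimated correlation). Among interferon-responsive genes, 14 of 23 tested members rose, 2 fell and the other 7 did not pass, and adjusted over the list alone 15 rose and 2 fell, with Usp18 (2.52 ± 0.14) and Isg20 (1.90 ± 0.12). The interferon list had a median log2 change of 0.54 (0.46 with bounds), camera adjusted p = 0.00223 (0.167 with an estimated correlation). Among chaperones of the endoplasmic reticulum, 2 of 25 tested members rose, 7 fell and the other 16 did not pass, and adjusted over the list alone 2 rose and 7 fell. The endoplasmic reticulum list had a median log2 change of -0.31, camera adjusted p = 0.00223 (0.141 with an estimated correlation). The chaperones Hspa5 (-0.82 ± 0.11) and Calr (-0.88 ± 0.11) fell, while the stress-induced Herpud1 (1.18 ± 0.12) and Dnajb9 (0.95 ± 0.10) rose.

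In fatty acid synthesis and oxidation, 6 of 28 tested members rose, 15 fell and the other 7 did not pass, and adjusted over the list alone 6 rose and 17 fell, with the desaturases Fads2 (-2.02 ± 0.13) and Scd2 (-1.40 ± 0.10). The fatty acid list had a median log2 change of -0.44, camera adjusted p = 0.00223 (0.167 with an estimated correlation). The median was -0.28 with normexp. In DNA replication, 3 of 37 tested members rose, 12 fell and the other 22 did not pass, and adjusted over the list alone 3 rose and 12 fell, with Tyms (-0.92 ± 0.14). DNA replication had a median log2 change of -0.22 (-0.37 scaled by the median), camera adjusted p = 0.00362 (0.141 with an estimated correlation). In mitosis, 1 of 30 tested members rose, 11 fell and the other 18 did not pass, and adjusted over the list alone 1 rose and 11 fell, with Cdc20 (-1.04 ± 0.14) and Ccnb1 (-0.95 ± 0.10). Mitosis had a median log2 change of -0.21, camera adjusted p = 0.00256 (0.167 with an estimated correlation). The median was -0.35 scaled by the median and -0.10 with quantile normalization. Among p53 targets, 10 of 21 tested members rose, 1 fell and the other 10 did not pass, and adjusted over the list alone 10 rose and 2 fell, with Aen (1.68 ± 0.15), Mdm2 (1.55 ± 0.16) and the brightest probe of Cdkn1a (2.89 ± 0.13), whose other probe did not pass (0.28 ± 0.12). The p53 list had a median log2 change of 0.48 (0.28 with bounds), camera adjusted p = 0.0305 (0.167 with an estimated correlation). The median was 0.30 with normexp. Among pan-neuronal genes, 8 of 10 tested members rose, 1 fell and the other 1 did not pass, and adjusted over the list alone 8 rose and 1 fell, with Uchl1, an abundant neuronal deubiquitinase (2.47 ± 0.09), and the tubulin Tubb3 (1.77 ± 0.16). The pan-neuronal list had a median log2 change of 0.89, camera adjusted p = 0.00261 (0.167 with an estimated correlation). The median was 0.50 with normexp. Among microglia and macrophage markers, 6 of 11 tested members rose and the other 5 did not pass, and adjusted over the list alone 6 rose. The microglia list had a median log2 change of 0.76 (0.52 with bounds), camera adjusted p = 0.0334 (0.167 with an estimated correlation). The median was 0.32 with normexp. The MHC class II chain gene Cd74 was at least 3.27-fold higher (log2 fold change 1.31 with normexp). Among oligodendrocyte markers, 6 of 10 tested members rose and the other 4 did not pass, and adjusted over the list alone 6 rose and 1 fell. The oligodendrocyte list had a median log2 change of 0.62 (0.50 with bounds), camera adjusted p = 0.047 (0.208 with an estimated correlation). The median was 0.12 with normexp. The growth factor receptor gene Pdgfra was at least 1.43-fold higher (log2 fold change 0.39 with normexp). Th had a log2 fold change of 0.11 ± 0.10 (adjusted p = 0.414). Mt1 (1.97 ± 0.08), Mt2A (0.57 ± 0.10), Slc30a1 (0.83 ± 0.08) and Atf3 (0.55 ± 0.09) rose. Hmox1 (0.65 ± 0.22), Nr4a2 (-0.08 ± 0.12), Tfrc (0.06 ± 0.12), Slc2a1 (0.24 ± 0.09) and Ndufs1 (-0.14 ± 0.11) did not pass. The 3-NPA arrays lay in another slide row than control and alone were extracted in a later run. They also lay in other columns, so 3-NPA and column cannot be told apart. Log2 changes had an SD of 0.0729 over 7 spike-in probes and 0.747 over genes. This argues against slide row or the later run as the cause, except on areas, dim signals or single probes. The count of 6477 fell to 3596 without 3-NPA replicate 1 and 3668 without 3-NPA replicate 2. Without control replicate 2 the calls of complexes II to V (adjusted p = 0.0667), the p53 targets (0.0998), the oligodendrocyte markers (0.115) and Sdhb (0.0532) were lost. Without 3-NPA replicate 2, those of the oligodendrocyte (0.0711) and microglia markers (0.0625), Sdhb (0.0987) and Ldha (0.0514) were lost, without 3-NPA replicate 1 those of Sdhb (0.067) and Mt2A (0.0509), and without either Mn array that of the oligodendrocyte markers (0.0532). The last also ended with normexp (0.221), quantile normalization (0.139), the trend and robust variance model (0.102), the deposited value table (0.124) and without probes with discordant spots (0.314). The call of the microglia markers also ended with normexp (0.0578), quantile normalization (0.0823), the deposited value table (0.0578) and probes well above background on all 8 arrays (0.297). That of complexes II to V ended with quantile normalization (0.175), and that of pan-neuronal genes with the looser rule on background (0.0582). With no filter on dim probes the lists of endoplasmic reticulum chaperones, complex I, complexes II to V, the tricarboxylic acid cycle, fatty acids, DNA replication, mitosis, microglia markers and pan-neuronal genes did not pass, the last with a median turned to -0.80. Pdgfra did not pass in the deposited value table (log2 fold change 0.21, adjusted p = 0.777).

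**Figure D3:**
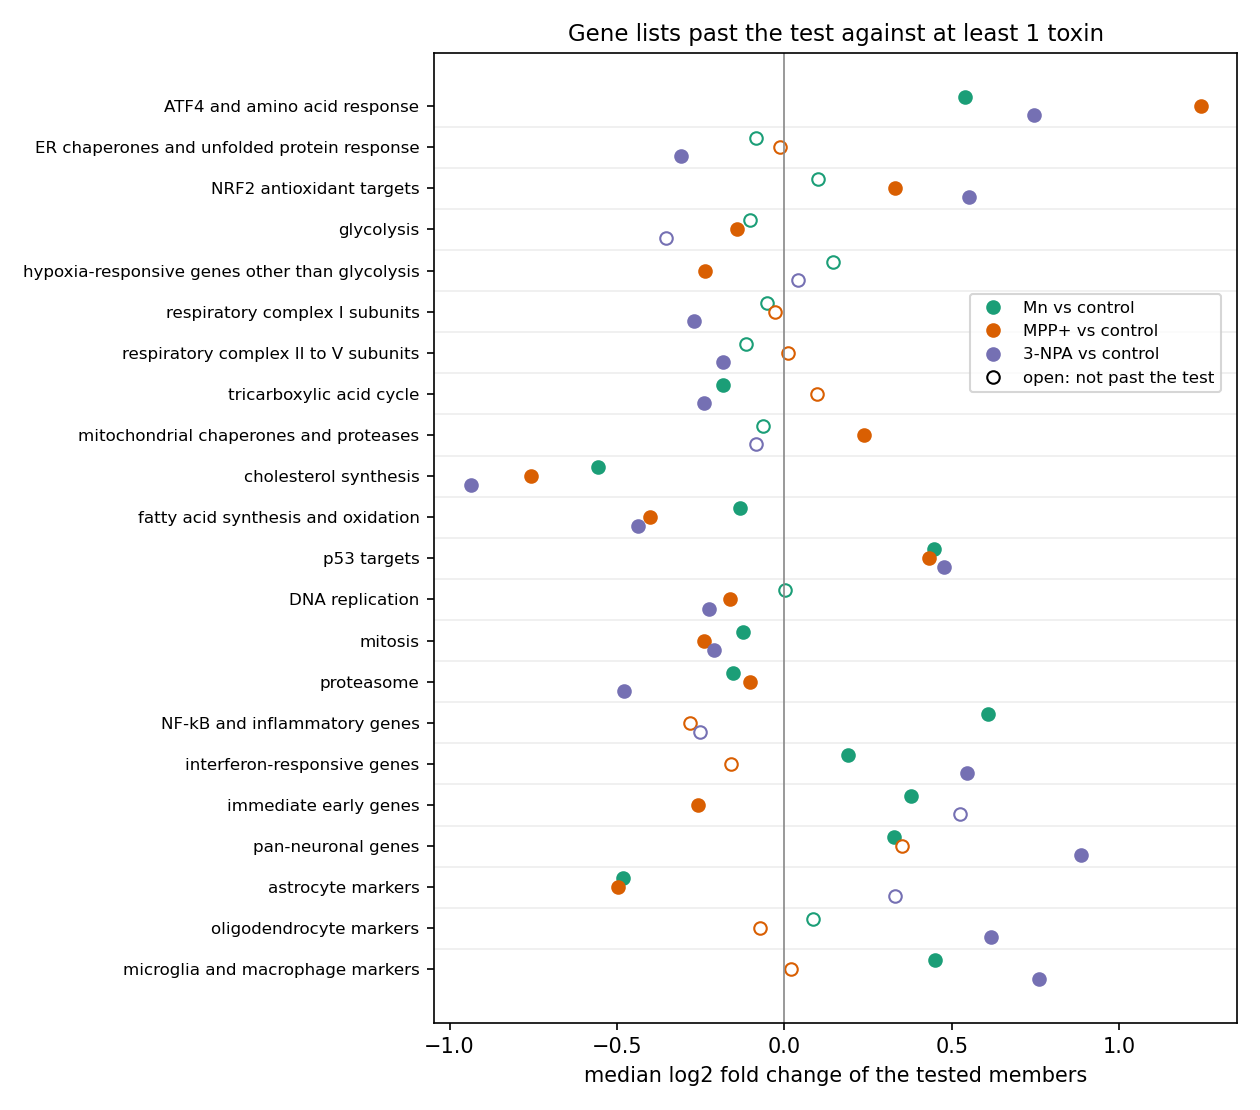
Median log2 fold change of the tested members of each gene list that passed camera against control with at least 1 toxin (horizontal axis), with filled points for lists that passed and open points for lists that did not. The ATF4 and amino acid response lay at 0.54 with Mn, 1.24 with MPP+ and 0.74 with 3-NPA, cholesterol synthesis at -0.56, -0.76 and -0.94, and the proteasome at -0.15, -0.10 (0.01 with scaling by the median) and -0.48.

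The comparison of Mn with MPP+ tests directly which responses differ between these toxins. Mgp was 24.5-fold higher with Mn (4.62 ± 0.13), Fos 18.6-fold (4.21 ± 0.19) and Egr2 13.1-fold (3.71 ± 0.19), while Cox6a2 was 15.6-fold lower (-3.96 ± 0.16) and the arginase gene Arg2 8.03-fold (-3.01 ± 0.10). Among 1536 called genes, 826 were higher and 710 lower with Mn. In the ATF4 list, 24 of 37 tested members were lower and the other 13 did not pass, and adjusted over the list alone 33 were lower, with Ddit3 (-1.92 ± 0.11), Trib3 (-1.56 ± 0.13) and Pck2 (-1.08 ± 0.08). The ATF4 list had a median log2 change of -0.63, camera adjusted p = 2.2e-16 (0.0331 with an estimated correlation). In the NF-kB list, 14 of 21 tested members were higher and the other 7 did not pass, and adjusted over the list alone 18 were higher, with the chemokines Ccl7 (2.89 ± 0.14) and Cxcl2 (2.48 ± 0.13). The NF-kB list had a median log2 change of 0.93, camera adjusted p = 6.6e-14 (0.0331 with an estimated correlation). Among immediate early genes, 12 of 24 tested members were higher and the other 12 did not pass, and adjusted over the list alone 14 were higher, with Ier2 (2.69 ± 0.14) and Egr1 (2.98 ± 0.16). The immediate early list had a median log2 change of 0.64, camera adjusted p = 9.75e-11 (0.104 with an estimated correlation). Among hypoxia-responsive genes, 8 of 23 tested members were higher and the other 15 did not pass, and adjusted over the list alone 14 were higher and 2 lower, with Angptl4 (1.22 ± 0.08) and Bhlhe40 (1.55 ± 0.11). The hypoxia list had a median log2 change of 0.47, camera adjusted p = 7.28e-06 (0.0598 with an estimated correlation). Among fibroblast and matrix genes, 8 of 20 tested members were higher and the other 12 did not pass, and adjusted over the list alone 11 were higher and 2 lower, with the collagen Col1a1 (1.75 ± 0.10) and Timp1 (1.11 ± 0.08). The matrix list had a median log2 change of 0.52 (0.35 with normexp), camera adjusted p = 1.8e-05 (0.0598 with an estimated correlation). The count fell to 652 without Mn replicate 1, 992 without Mn replicate 2, 276 without MPP+ replicate 1, 210 without MPP+ replicate 2 and 645 without either 3-NPA array. It was 309 with only the 4 arrays of the pair, 579 with no filter on dim probes and 2350 with the trend and robust variance model.

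Mn against 3-NPA gave 4843 called genes, 1982 higher and 2861 lower with Mn. The higher share was 40.9%, and 66.8% with scaling by the median. Csf2 was at least 9.84-fold higher with Mn, Mgp 14.0-fold (3.81 ± 0.13), Ccl20 9.24-fold (3.21 ± 0.16) and the adhesion gene Vcam1 6.71-fold (2.75 ± 0.20). Ldhb was 32.1-fold lower (-5.01 ± 0.13), Mro at least 19.5-fold and Gsta1 at least 10.8-fold. With normexp the log2 fold changes were 1.48 (Csf2), -3.14 (Ldhb), -2.42 (Mro) and -1.80 (Gsta1). In the NF-kB list, 17 of 21 tested members were higher, 1 lower and the other 3 did not pass, and adjusted over the list alone 17 were higher and 2 lower, with Cxcl2 (2.74 ± 0.13) and Cxcl1 (1.73 ± 0.09). The NF-kB list had a median log2 change of 0.99, camera adjusted p = 1.05e-08 (0.0808 with an estimated correlation). In the proteasome, 13 of 31 tested members were higher and the other 18 did not pass, and adjusted over the list alone 14 were higher, with Psmd14 (0.97 ± 0.09). The proteasome had a median log2 change of 0.30, camera adjusted p = 3.3e-07 (0.0815 with an estimated correlation). The median was 0.52 scaled by the median. In complex I, 8 of 36 tested members were higher and the other 28 did not pass, and adjusted over the list alone 8 were higher. Complex I had a median log2 change of 0.20, camera adjusted p = 0.000357 (0.33 with an estimated correlation). The median was 0.42 scaled by the median. Among NRF2 targets, 12 of 26 tested members were lower and the other 14 did not pass, and adjusted over the list alone 12 were lower, with Gsta4 (-1.51 ± 0.11) and Srxn1 (-1.39 ± 0.11). The NRF2 list had a median log2 change of -0.48, camera adjusted p = 0.000392 (0.175 with an estimated correlation). The median was -0.26 scaled by the median. The count fell to 2254 without 3-NPA replicate 1 and 2137 without 3-NPA replicate 2.

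MPP+ against 3-NPA gave 5244 called genes, 2181 higher and 3063 lower with MPP+. The higher share was 41.6%, and 72.2% with scaling by the median. Both compounds act on the respiratory chain. Of the 35 lists, 15 passed, and 0 did with an estimated correlation. Cox6a2 was 6.95-fold higher with MPP+ (2.80 ± 0.16) and Ccl20 7.4-fold (2.89 ± 0.16), while Ldhb was 30.8-fold lower (-4.95 ± 0.13) and Gsta1 at least 17.1-fold (log2 fold change -1.89 with normexp). Among immediate early genes, 16 of 24 tested members were lower and the other 8 did not pass, and adjusted over the list alone 16 were lower, with Fos (-3.33 ± 0.19) and the neuronal activity gene Arc (-2.92 ± 0.15). The immediate early list had a median log2 change of -0.89, camera adjusted p = 3.59e-07 (0.157 with an estimated correlation). Among interferon-responsive genes, 2 of 23 tested members were higher, 18 lower and the other 3 did not pass, and adjusted over the list alone 2 were higher and 18 lower, with Isg15 (-1.47 ± 0.09) and Isg20 (-1.73 ± 0.12). The interferon list had a median log2 change of -0.64 (-0.38 scaled by the median), camera adjusted p = 1.15e-05 (0.131 with an estimated correlation). In the ATF4 list, 19 of 37 tested members were higher, 1 lower and the other 17 did not pass, and adjusted over the list alone 24 were higher and 1 lower, with Pck2 (1.45 ± 0.08) and Trib3 (1.17 ± 0.13). The ATF4 list had a median log2 change of 0.42 (0.68 scaled by the median), camera adjusted p = 3.59e-07 (0.131 with an estimated correlation). In the proteasome, 14 of 31 tested members were higher and the other 17 did not pass, and adjusted over the list alone 16 were higher, with Psmd14 (1.13 ± 0.09). The proteasome had a median log2 change of 0.37 (0.63 scaled by the median and 0.20 with quantile normalization), camera adjusted p = 3.59e-07 (0.131 with an estimated correlation). In the tricarboxylic acid cycle, 10 of 23 tested members were higher and the other 13 did not pass, and adjusted over the list alone 14 were higher, with Sucla2 (1.01 ± 0.09) and Pdhb (0.82 ± 0.11). The list had a median log2 change of 0.32 (0.58 scaled by the median and 0.20 with quantile normalization), camera adjusted p = 3e-05 (0.131 with an estimated correlation). In complex I, 11 of 36 tested members were higher and the other 25 did not pass, and adjusted over the list alone 11 were higher. Complex I had a median log2 change of 0.23 (0.48 scaled by the median and 0.09 with quantile normalization), camera adjusted p = 5.17e-05 (0.23 with an estimated correlation). Among mitochondrial chaperones and proteases, 8 of 17 tested members were higher and the other 9 did not pass, and adjusted over the list alone 10 were higher, with Lonp1 (1.34 ± 0.16) and Hspa9 (0.95 ± 0.11). The mitochondrial chaperone list had a median log2 change of 0.34, camera adjusted p = 0.000432 (0.131 with an estimated correlation). The median was 0.59 scaled by the median. The count fell to 2439 without MPP+ replicate 1, 2264 without MPP+ replicate 2, 2428 without 3-NPA replicate 1 and 2431 without 3-NPA replicate 2, and it was 7997 with array weights.

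Across the 3 toxins, 492 genes passed in the same direction, 309 higher and 183 lower, where independent lists of the same sizes would share 12.7 and 5.53. The higher share was 62.8%, 76.9% after quantile normalization and 46.3% with the normexp background correction. The brightest probe of Slc7a11 rose with each, and its far dimmer probe did not pass (0.58 ± 0.32 with Mn, 0.87 ± 0.32 with MPP+ and 0.64 ± 0.32 with 3-NPA). The mean over both probes was 2.0, 2.46 and 2.26. Cox6a2 had log2 fold changes of 2.31 ± 0.16 with Mn, 6.27 with MPP+ and 3.47 ± 0.16 with 3-NPA. Gpnmb, a glycoprotein of lysosomes and melanosomes, rose by 2.10 ± 0.10, 2.10 ± 0.10 and 3.81 ± 0.10, Slc7a3 by 2.02 ± 0.14, 3.39 ± 0.14 and 2.50 ± 0.14, and Mgmt by 2.29 ± 0.29, 3.21 ± 0.29 and 3.73 ± 0.29. Among genes that fell with each toxin, the transsulfuration enzyme Cbs had log2 fold changes of -1.90 ± 0.14, -2.41 ± 0.14 and -2.60 ± 0.14, and C5 of -1.96 ± 0.19, -2.54 ± 0.19 and -2.90 ± 0.19. The amino acid transporter Slc38a4 had values of -1.63 ± 0.19, -1.83 ± 0.19 and -1.76 ± 0.19. With normexp the log2 fold changes with Mn, MPP+ and 3-NPA were -0.83, -1.11 and -1.0 for Cbs, -1.02, -1.35 and -1.31 for C5, and -1.0, -1.22 and -1.09 for Slc38a4. Those of Mgmt were 1.33, 2.01 and 2.49. Unchanged groups simulated 100 times against the same controls had 0.0633 calls per comparison, so their shared count of 0 says little. Their top genes, in lists of the observed sizes, shared 234 higher and 161 lower genes on average and 267 and 193 at most. As these were not calls, how much overlap comes from shared controls stays open. Across genes, the log2 fold changes of Mn and MPP+ correlated at 0.547, those of Mn and 3-NPA at 0.494 and those of MPP+ and 3-NPA at 0.421, against 0.501, 0.502 and 0.499 for simulated unchanged groups. The covariances were 0.143, 0.186 and 0.163 against 0.0314, 0.0315 and 0.0314 simulated, differences of 0.112, 0.155 and 0.131. The 2 control arrays are too few to be split into sets of at least 2, so part of these correlations and of the overlaps below may come from the shared controls. With 1 control array for each toxin, the correlations were 0.224 and 0.274 (Mn and MPP+), 0.269 and 0.290 (Mn and 3-NPA) and 0.231 and 0.211 (MPP+ and 3-NPA). This choice removes shared arrays but not what both controls have in common. By pairs, Mn and MPP+ shared 346 higher and 307 lower genes (56.9 and 34.6 for independent lists) with 50 in opposite directions. Mn and 3-NPA shared 600 and 277 (170 and 85.3) with 152 opposite. They also shared slide columns, which may add to this and to their correlation. MPP+ and 3-NPA shared 840 and 549 (282 and 176) with 234 opposite. The count of 492 was 268 without Mn replicate 1, 177 without MPP+ replicate 1, 157 without MPP+ replicate 2, 239 without 3-NPA replicate 1, 240 without 3-NPA replicate 2 and 221 with array weights.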

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

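The tests on negative control spots, on dim probes, on probes well above background on all 8 arrays, on the position of arrays in the slide columns and on transcripts shared by same-numbered samples were chosen after the result was seen, while those on spike-ins, cell type markers and different spots of a probe were set before it. The share of spots well above background, a mark no comparison of the report tests, was higher in each toxin group than in control. The group means were 37998.5 spots for Mn, 40422.5 for MPP+ and 40849.5 for 3-NPA, against 33385.5 in control.

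Without the filter on dim probes, most called genes fell with each toxin. The 10868 probes that the filter left out had median log2 changes of -1.41 with Mn, -2.0 with MPP+ and -1.74 with 3-NPA, and negative control spots, which target no rat transcript, changed by -1.47, -2.16 and -1.90, at least 104% of those medians. This is consistent with a higher lower end of signal on the control arrays. With normexp the median of the same probes was -0.0617 with Mn, -0.0430 with 3-NPA and -0.23 with MPP+, where spike-ins averaged -0.29. The normexp offset of 50 shrinks changes of dim signals, so a lower abundance of rare transcripts stays open. So does a difference in scaling with MPP+.

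3-NPA was followed by more called genes than Mn or MPP+. Spike-in RNA, added before labelling by the makers' design, had an SD of log2 changes of 0.0729 over 7 probes against 0.747 over genes. This argues against labelling, hybridisation, slide row or the later run as the cause, except on areas, dim signals or single probes, which 7 probes cannot show. Among probes well above background on all 8 arrays, 3-NPA still had 2.29 times the calls of MPP+, which argues against the raised lower end on the control arrays. Of 14 abundant markers of other brain cell types, 4 passed toward higher values (Tyrobp, Cd74, Mbp and Pecam1, at levels of -3.80, -2.90, -4.74 and -4.72 in log2 relative to the array's 75th percentile). All were dim in control, whose lowest signals well above background were -4.79 and -4.43, so no rise can be stated for Mbp and Pecam1. Another 7 were not well above background on any 3-NPA array, while C1qb, Mobp and Aqp4 were on both. Some marker lists also passed with 3-NPA, so RNA of another cell type stays open. A toxin effect, slide column, the unstated dose and time of 3-NPA and a separate culture or RNA batch may each remain and were not tested.

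Replicates 1 and 2 of Mn and of 3-NPA differed in the same genes, with a correlation over genes of 0.499 (Spearman 0.261) between the replicate differences, and genes are not independent replicates. For probes with a pair of spots, the correlation was 0.331 with the same spot and 0.03 with different spots, 10.3% of that value, which is consistent with bright or dim areas at the same place on these arrays. The replicate differences of control and MPP+ correlated at 0.0243, which had been set as evidence against the position of arrays in the slide columns. That reading was wrong, because a defect confined to the columns that hold the Mn and 3-NPA arrays would leave control and MPP+ uncorrelated. The column and the areas on the arrays cannot be told apart. A transcript difference shared by the same-numbered samples would show in both spots of a probe, so the fall to 10.3% argues against it for these probes.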

How the results depend on the processing

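The looser rule on background, the removal of probes with discordant spots, the 6 arrays of the first run and the tests of single lists under each setting were chosen after seeing the data. Over all alternatives, 5204 of 5326 values of the 238 named gene results kept their side of the threshold, 98 (48 results) no longer passed and 24 (9 results) passed. Only uncalled genes, such as Th, changed sign. For the 105 lists, 2376 of 2584 values kept their side, 120 (39 lists) no longer passed, 83 (33 lists) passed and 5 turned. Those were DNA replication (-0.16) and proteasome (-0.10) with MPP+ when no dim probe was left out, where the test turned upward because the other genes fell more. With fry they were metallothioneins (-0.0498), iron handling (-0.0514) and YAP and TGF-beta targets (0.10) with 3-NPA. The cause was not tested except where named.

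By normexp the correlations of fold changes were 0.50 (Mn and MPP+), 0.562 (Mn and 3-NPA) and 0.475 (MPP+ and 3-NPA), by quantile normalization 0.654, 0.633 and 0.590, with probes well above background on all 8 arrays 0.485, 0.559 and 0.499, and from the deposited values 0.587 (Mn and MPP+) and 0.459 (MPP+ and 3-NPA). With discordant spots left out the last was 0.440. With no filter on dim probes 7055 genes were called for Mn, 8845 for MPP+, 11934 for 3-NPA, 579 for Mn against MPP+ and 5292 in the same direction for all 3 toxins. The correlations were then 0.829, 0.792 and 0.799, and 7 lists passed for MPP+ and 9 for 3-NPA. Trend and robust variances gave 2350 genes for Mn against MPP+. Array weights gave 439 for Mn, 7997 for MPP+ against 3-NPA and 221 for all 3. With only the 4 arrays of a pair, and so fewer arrays for the spread, 6 genes were called for Mn, 987 for MPP+ and 309 for Mn against MPP+, and the overlap of 3 toxins was not run. The 6 arrays of the first run gave 653, 1288 and 645. Changes of at least 2-fold, by construction fewer, numbered 466 (Mn), 640 (MPP+), 2039 (3-NPA), 400 (Mn against MPP+), 1466 (Mn against 3-NPA) and 1491 (MPP+ against 3-NPA). Camera with an estimated correlation called 2 lists for Mn, 1 for MPP+ and 0 for 3-NPA, and fry 22, 21 and 31.

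Leaving out each array, with the lone array of a group assumed to vary like the other groups, gave 569 to 1276 genes for Mn, 477 to 2387 for MPP+, 3596 to 6715 for 3-NPA, 210 to 1706 for Mn against MPP+, 2137 to 5335 for Mn against 3-NPA, 2264 to 5772 for MPP+ against 3-NPA and 157 to 601 for all 3. At the lowest counts, 458, 452, 3532, 195, 2089 and 2217 genes were shared with the full fit. The correlations ran from 0.474 to 0.660, 0.437 to 0.585 and 0.398 to 0.523, and the lists from 11 to 16 for Mn, 8 to 15 for MPP+ and 13 to 17 for 3-NPA. With the replicate number as a block, 997 genes were called for Mn, 2050 for MPP+, 6297 for 3-NPA, 1220 for Mn against MPP+, 4553 for Mn against 3-NPA, 5072 for MPP+ against 3-NPA and 396 for all 3. The block ended the calls of glycolysis and DNA replication with MPP+ and of Mt1, Ddit3 and Atf3 with Mn. Same-numbered arrays deviated together at -0.02 (control and Mn), 0.02 (control and MPP+), 0.03 (control and 3-NPA), 0.10 (Mn and MPP+), 0.50 (Mn and 3-NPA) and 0.09 (MPP+ and 3-NPA). These values gave no sign of a pairing with control, and whether same-numbered samples were paired stays unknown. Signal over background limits what can be said of genes dim in control, where the lowest signals lay highest, and their folds are bounds.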

Other observations

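Other gene groups fixed in advance held called members after 3-NPA. In glycolysis, 2 of 22 tested members rose, 10 fell and the other 10 did not pass, and adjusted over the list alone 5 rose and 12 fell, with the lactate exporter Slc16a3 (-1.03 ± 0.09) and the kinases Pgk1 (-0.83 ± 0.10) and Pkm (-0.76 ± 0.13). Glycolysis had a median log2 change of -0.35, camera adjusted p = 0.0508 (0.172 with an estimated correlation). The median was -0.23 with quantile normalization. In autophagy and lysosome, 12 of 35 tested members rose, 4 fell and the other 19 did not pass, and adjusted over the list alone 13 rose and 4 fell, with the autophagosome gene Gabarapl1 (1.32 ± 0.10, and 0.67 ± 0.22 for a dimmer probe, which did not pass), the conjugating enzyme Atg3 (-1.15 ± 0.10) and the lysosomal cholesterol transporter Npc1 (1.01 ± 0.10). The autophagy list had a median log2 change of 0.20, camera adjusted p = 0.265 (0.32 with an estimated correlation). The median was 0.06 scaled by the median. Among immediate early genes, 12 of 24 tested members rose, 5 fell and the other 7 did not pass, and adjusted over the list alone 13 rose and 5 fell, with Fosl1 (2.75 ± 0.18) and Junb (-1.43 ± 0.13). The immediate early list had a median log2 change of 0.52, camera adjusted p = 0.106 (0.487 with an estimated correlation). The median was 0.34 with normexp. In iron handling, 7 of 21 tested members rose, 3 fell and the other 11 did not pass, and adjusted over the list alone 8 rose and 5 fell, with the iron exporter Slc40a1 (1.46 ± 0.10), the mitochondrial importer Slc25a37 (1.66 ± 0.18, and 1.08 with normexp) and the importer Slc11a2 (-0.98 ± 0.08). Iron handling had a median log2 change of -0.05, camera adjusted p = 0.938 (0.947 with an estimated correlation). The mean was 0.23. The median was -0.19 scaled by the median, -0.03 with quantile normalization and -0.13 with normexp. Among dopaminergic genes, 4 of 15 tested members rose, 1 fell and the other 10 did not pass, and adjusted over the list alone 4 rose and 1 fell, with Ddc, the decarboxylase that makes dopamine, at least 2.83-fold higher (log2 fold change 0.88 with normexp). The dopaminergic list had a median log2 change of 0.11, camera adjusted p = 0.607 (0.652 with an estimated correlation). The median was -0.04 scaled by the median, 0.04 with quantile normalization and 0.03 with normexp.

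The collagen crosslinker Lox fell with each (-1.41 ± 0.11 with Mn, -1.72 ± 0.11 with MPP+ and -1.63 ± 0.11 with 3-NPA). The brightest probe of Hrk, a gene of the BCL-2 family that promotes apoptosis, was at least 2.02-fold higher with MPP+ and 3.08-fold with 3-NPA. Its other probe, at a similar level, did not pass (-0.15 ± 0.23 and 0.34 ± 0.23), and with normexp its log2 fold changes were 0.91 and 1.36. Among YAP and TGF-beta targets, the matricellular gene Ccn2 (2.06 ± 0.14) rose with Mn, and the list did not pass. The YAP list had a median log2 change of 0.02, camera adjusted p = 0.187 (0.509 with an estimated correlation). The median was 0.09 scaled by the median, 0.07 with quantile normalization, -0.00412 with normexp and 0.03 in the deposited value table. Id2 fell with each toxin (-1.50 ± 0.16, -1.68 ± 0.16 and -2.49). With only the 4 arrays of Mn and control, Lox, Ccn2 and Id2 did not pass (adjusted p = 0.0539, 0.0524 and 0.0722).

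All tests that follow were chosen after the result was seen, on lists written after the values of some members were known, and the members noticed when the lists were written were left out, though some others had been seen. Left out of the histone list were Hist1h2bq, Hist1h2bf, H1f1 and H1f0, which had log2 fold changes of -2.98 ± 0.16, -2.94 ± 0.09, -2.44 ± 0.28 and 0.52 ± 0.10 with 3-NPA. Of the other 25 tested histone genes, 1 rose and 7 fell with Mn, 2 and 9 with MPP+ and 1 and 13 with 3-NPA. Their medians were -0.22 (-0.14 with scaling by the median and -0.0988 with quantile normalization), -0.10 (0.01 with scaling by the median) and -0.95, with camera adjusted p = 0.00553, 0.0125 and 5.3e-05, and adjusted p = 0.499, 0.312 and 0.162 with an estimated correlation. A hypothesis in line with these values, the least of which was -0.10, is that histone transcripts were lower. The 21 without H2aj, H1fx, H1f8 and H2ap, which are not known to depend on replication, had medians of -0.48 (-0.27 with normexp), -0.10 and -0.99. The value for MPP+ again turned to 0.01 with scaling by the median, so a fall of replication-dependent ones stays open.

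Of 11 tested genes of the aryl hydrocarbon receptor response, without Cyp1a1 and Nqo1, 1 rose with Mn, 5 with MPP+ and 9 with 3-NPA. The medians were 0.32, 0.38 and 1.03 (0.62 with normexp), with camera adjusted p = 0.00553, 0.0125 and 0.000141, and adjusted p = 0.14, 0.209 and 0.0329 with an estimated correlation. With 3-NPA, Ahrr, a repressor of the receptor, rose by 1.21 ± 0.12, Tiparp by 0.92 ± 0.10 and Aldh3a1 by 1.42 ± 0.12. Activity of this receptor with all 3 toxins may be a hypothesis from these values (least median 0.32), and receptor activity was not measured.

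Germ-line genes were set against the hypothesis that such genes rose with 3-NPA through loss of silencing. Left out were Taf7l, which rose, and Tex19.1, which fell with MPP+ (-2.76 ± 0.23) and 3-NPA (-1.45 ± 0.23). Of 17 others tested, 4 rose and 3 fell, with a median of 0.0823 (-0.06 with scaling by the median and -0.02 with normexp) and camera adjusted p = 0.948, and the list did not pass. Complement and coagulation genes other than C5, Kng1, Kng2 and C4bpa (-1.83 ± 0.30 with Mn, -2.48 ± 0.30 with MPP+ and -1.67 ± 0.30 with 3-NPA for the last) were set against the hypothesis of a shared fall. Of 26 tested, 2 rose and 1 fell with Mn, 5 and 7 with MPP+ and 16 and 4 with 3-NPA, where the median was 0.87 (0.34 with normexp, camera adjusted p = 0.000205, adjusted p = 0.0329 with an estimated correlation), against that hypothesis.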
